A study of Mus musculus with 17 samples.

How the data were processed

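Total RNA from cultured neural precursor cells of the adult mouse hippocampus was measured on 17 Illumina bead arrays. Per the labels' protocols, cells proliferated in medium with basic fibroblast growth factor and epidermal growth factor, both factors were withdrawn to start differentiation, and RNA was amplified and labelled with biotin with the Illumina TotalPrep kit. The labels give 1 array for each of 17 times from 0 to 720 min, and 0 min is the proliferating culture. No time was measured more than once, and no array came from a culture kept in growth factors for a matching time.

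The deposited values are on a log2 scale, as read from their range of 5.14 to 15.47, since the labels state no unit. The scanner software, background correction and normalization method are not given in the sources used here. The sorted values were nearly the same on the 17 arrays, with a largest spread of 0.135 at 1 rank, and the array medians lay between 6.40 and 6.42. The values were therefore used without further scaling. The lowest correlation between 2 arrays over all probes was 0.972. No detection p-value accompanied the values, so a probe near the lower end cannot be separated from background, and the number of arrays limits the precision.

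The table held 19949 probes. Of these, 18351 had 1 gene symbol, 0 had several and 1598 were unnamed. Symbols came from the platform annotation and were updated through gene identifiers for 16482 probes and through accessions for 956, with the mouse RefSeq gene table of GRCm38.p6, while 913 were kept as given, and 305 symbols changed. There were 18256 named genes, of which 95 had more than 1 probe, and the probe with the highest mean stood for the gene. Probes with a mean below the median of all probes, 6.41, were left out, which kept 9940 features, 9207 of them named.

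Tests used limma 3.58.1 in R 4.3.3. The time course was tested with a moderated F test of a natural cubic spline with 4 degrees of freedom over the square root of minutes. The 17 times were also grouped into an early window of 0 to 60 min (5 arrays), a second window of 90 to 180 min (4 arrays), the third window of 240 to 360 min (3 arrays) and a late window of 420 to 720 min (5 arrays), and each later window was compared with the early one. Neighbouring times stood in for replicates, so each p-value measures the spread around a curve or within a window of 1 series of arrays, not the spread between independent cultures. The arrays at 15 to 60 min were also compared with the lone array at 0 min, which was assumed to vary like the others. Genes past the threshold had a Benjamini-Hochberg adjusted p under 0.05. A changing gene was called sustained if its fitted curve at 720 min still lay beyond the midpoint of its largest departure. Otherwise it was called transient, including when the curve had crossed its 0 min value.

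Of 26 gene lists that were fixed, 25 were tested with limma's camera, with a preset correlation between genes of 0.01, and p-values were adjusted over 75 tests, from these lists and 3 window comparisons. A list needed 3 members above the filter. The 11 microglia and macrophage markers on the array were all below it. The windows, tests, gene lists and most alternatives were fixed before the data were examined, as was the rule for the genes named. That rule took Atf3 and Atf4 always, the 10 largest rises and 10 largest falls in the late window among genes whose early and late arrays did not overlap, the 5 largest each way in the other windows and among transient genes, and up to 4 members per list with the largest change. Genes with placeholder symbols were passed over. The probe for Atf3 lay below the filter, with a mean of 6.24, and its values come from the same models run on 19854 features without the filter.

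The procedure was tested on simulated data with the real means of the 9940 features and independent noise of their spread around the fitted curves. Most simulated features did not change, and neighbouring arrays were not made alike. Real change within a window adds to the spread, so the simulated shares and false calls may be better than those of the real series. For the time course it recovered 11.9% of simulated changes of 0.3 on the log2 scale, 92.5% of those of 0.6 and 97.0% of those of 1, with 5 false calls. For the late window the shares were 32.8%, 100% and 98.5%, with 11 false calls, and for the third window 8.96%, 73.1% and 89.4%, with 7 false calls. The simulated changes began too late to test the second window, where 0 were recovered. Alternatives covered scaling, the filter on dim probes, the choice of probe, the variance model, array weights, the curve, the window limits, the set test and leaving out each array in turn.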

Results

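The series followed adult mouse hippocampal neural precursor cells through the first 720 min after withdrawal of basic fibroblast growth factor and epidermal growth factor, with 1 array at each of 17 times. Its title names the transcription factors Atf3 and Atf4 in early events before differentiation. Values are log2 signals. Means are given with the SD over the times of a window, and changes with the standard error (SE) of the model.

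Over the whole time course, 6152 of 9940 features changed (61.9%), 3057 upward and 3095 downward. Genes that rose and stayed up numbered 2431, and 2346 fell and stayed down. Both sets reached the midpoint of their change at a median of 300 min. A further 626 rose and 749 fell transiently, with a median midpoint of 120 min and a median peak of 240 min. Transient genes may have returned only in part by 720 min, or crossed to the other side of their 0 min value. Midpoints are read from the fitted curves. They were at 15 min for 155 of the transient rises and 156 of the falls, although 0 features differed between 15 to 60 min and 0 min. Among transient genes, Trib3, Chac1, Mfng, Nupr1 and Parm1 had the largest upward departures, and Aatk, Rassf3, Olig2, Plk2 and Prr18 the largest downward ones. Olig2, a transcription factor of the oligodendrocyte lineage, went from 9.18 at 0 min to 6.66 at 120 min and was at 9.04 at 720 min.

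The first principal component held 56.7% of the variance and the second 14.0%. The first stayed between -25.5 and -25.4 from 0 to 45 min, was -22.8 at 60 min and increased at each later time to 31.6 at 720 min. The second was at 8.91 at 0 min, between -16.3 and -16.1 from 180 to 300 min, and 19.3 at 720 min.

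**Figure D1:**
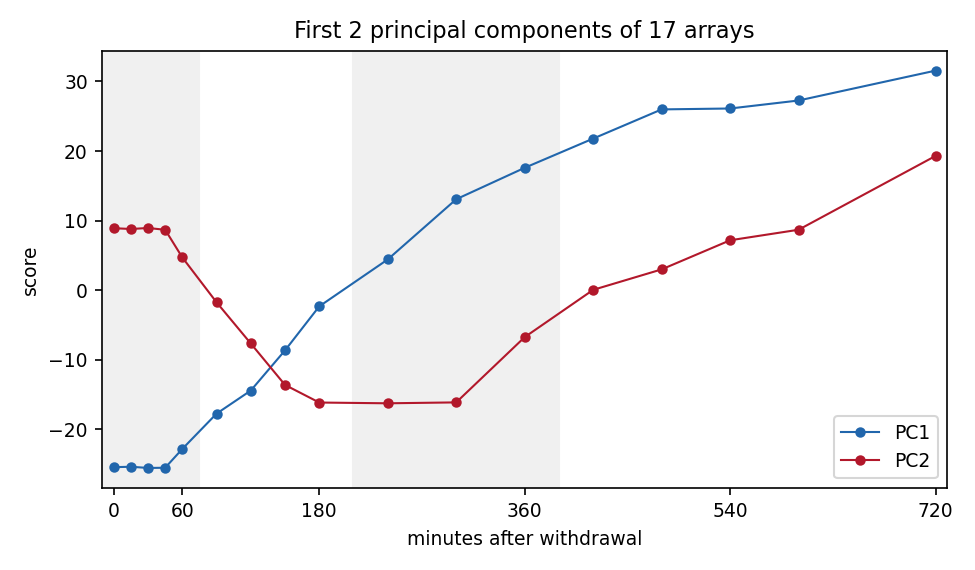
Scores of the first 2 principal components (vertical axis, no unit) of the 17 arrays against minutes after withdrawal, 1 point per array, with the early window and the third shaded. The first component moves from -25.4 at 0 min to 31.6 at 720 min, and the second is lowest, at -16.3, at 240 min.

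The first hour was compared with the proliferating culture to find the earliest responses. Atf4 was at 13.13 at 0 min and at 12.98 at 60 min, and Atf3 was at 5.83 and 6.30. Neither gene passed the test of 15 to 60 min against 0 min. Dusp6, a phosphatase that switches off ERK, was at 13.65 at 0 min, 12.32 at 45 min and 10.11 at 60 min. Egr1, an immediate early transcription factor, was at 13.26 at 0 min and 9.98 at 60 min. With limma, 0 of 9940 features differed between 15 to 60 min and 0 min, while 441 had an unadjusted p under 0.05. At the unadjusted threshold, chance alone gives at least as many features. This comparison rested on 1 array at 0 min and averaged 60 min with the 3 times before it.

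The second window, 90 to 180 min, was compared with the early window. Of 11 MAPK and growth factor feedback genes, 9 fell (camera adjusted p = 1.2e-10). Dusp6 went from 12.41 ± 1.38 (SD, n = 5 times) to 9.09 ± 0.76 (n = 4), and Egr1 from 12.38 ± 1.38 to 9.74 ± 0.82. The early means include the 60 min array, at which both genes were already lower. The MAPK list mean, relative to the early window, was 0.04 at 45 min and -0.67 at 60 min. The window differences therefore understate the fall from 0 min, which began before 90 min. Of 26 integrated stress response genes, 9 rose and 17 did not pass (camera adjusted p = 8.7e-09, and adjusted p = 0.29 with an estimated correlation). Chac1, a glutathione-degrading enzyme, was 6.76-fold higher and Trib3, a pseudokinase induced by Atf4, 4.73-fold higher. Atf4 itself rose from 12.95 ± 0.18 to 13.57 ± 0.07, and the dim Atf3 probe rose from 6.08 ± 0.19 to 6.77 ± 0.25.

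Of 9940 features, 1154 changed in the second window, 545 higher and 609 lower. The largest rises were in Chac1 (log2 change 2.76, SE 0.26, adjusted p = 2.7e-07), Trib3 (2.24), Gadd45g (2.19), Ddit4, an inhibitor of mTORC1 (2.11), and Bcl2l11, a pro-apoptotic BH3-only gene (2.05). The largest falls were in Dusp6 (-3.32, SE 0.45, adjusted p = 2.4e-05), Egr1 (-2.64), Irs2, an adaptor of the insulin receptor (-2.57), the transcription factor Pou3f1 (-2.54) and Irf2bpl (-2.02). Atf4 rose by 0.63 (SE 0.14, adjusted p = 0.0033). Without the filter, Atf3 rose by 0.69 (SE 0.11, adjusted p = 0.000283) and its highest value was 7.04 at 150 min, the time at which Atf4 reached 13.67. The Atf3 probe lay near background, at percentile 44.9 of the probes, so 0.69 is the measured difference and not an exact size of the change in transcript. Without the 180 min array 686 features passed.

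Of 11 MAPK and growth factor feedback genes, 9 fell and 0 rose in the second window, and 10 fell adjusted over the list alone (camera adjusted p = 1.2e-10). Dusp4 fell by 1.77 and Ier3 fell by 1.46 on the log2 scale. This list also passed with the correlation estimated (adjusted p = 0.0475 with an estimated correlation). In the list fixed for Atf4 and the integrated stress response, 9 of 26 also rose and 0 fell adjusted over the list alone. Nupr1 rose by 1.66. The separate list of 15 tRNA synthetase genes did not pass, with 0 higher and 1 lower (camera adjusted p = 0.895). Of 12 immediate early genes, 7 fell, among them Egr4 by 1.99, and 1, Klf4, rose by 1.38. The same counts held adjusted over the list alone (adjusted p = 4.9e-05), with adjusted p = 0.125 with an estimated correlation. Egr1 and Ier3 belong to both the immediate early and the MAPK lists, so these lists are not separate evidence. Of 18 ribosome biogenesis and MYC target genes, 7 fell, and 7 adjusted over the list alone, with Ppan down by -1.18 and Gnl3 by -0.78 (adjusted p = 4.5e-05, and adjusted p = 0.268 with an estimated correlation). Of 16 FOXO target genes, 6 rose and 1 fell, and 6 and 1 adjusted over the list alone (adjusted p = 0.0127, and adjusted p = 0.29 with an estimated correlation). Of 9 Notch pathway genes, 4 rose and 1 fell, or 5 and 2 adjusted over the list alone (adjusted p = 0.0241, and adjusted p = 0.29 with an estimated correlation). Of 11 NRF2 oxidative stress genes, 1, Srxn1, rose by 0.54, and 2 rose adjusted over the list alone (adjusted p = 0.0256, and adjusted p = 0.44 with an estimated correlation). Slc7a11, which the stress response list also holds, Osgin1 and Hmox1 of the NRF2 list had changes of 0.46, 0.43 and 0.28 that did not pass. Osgin1 passed when the array at 45 min (0.52), 60 min (0.51) or 180 min (0.55) was left out, and Hmox1 was at 0.16 without 180 min.

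**Figure D2:**
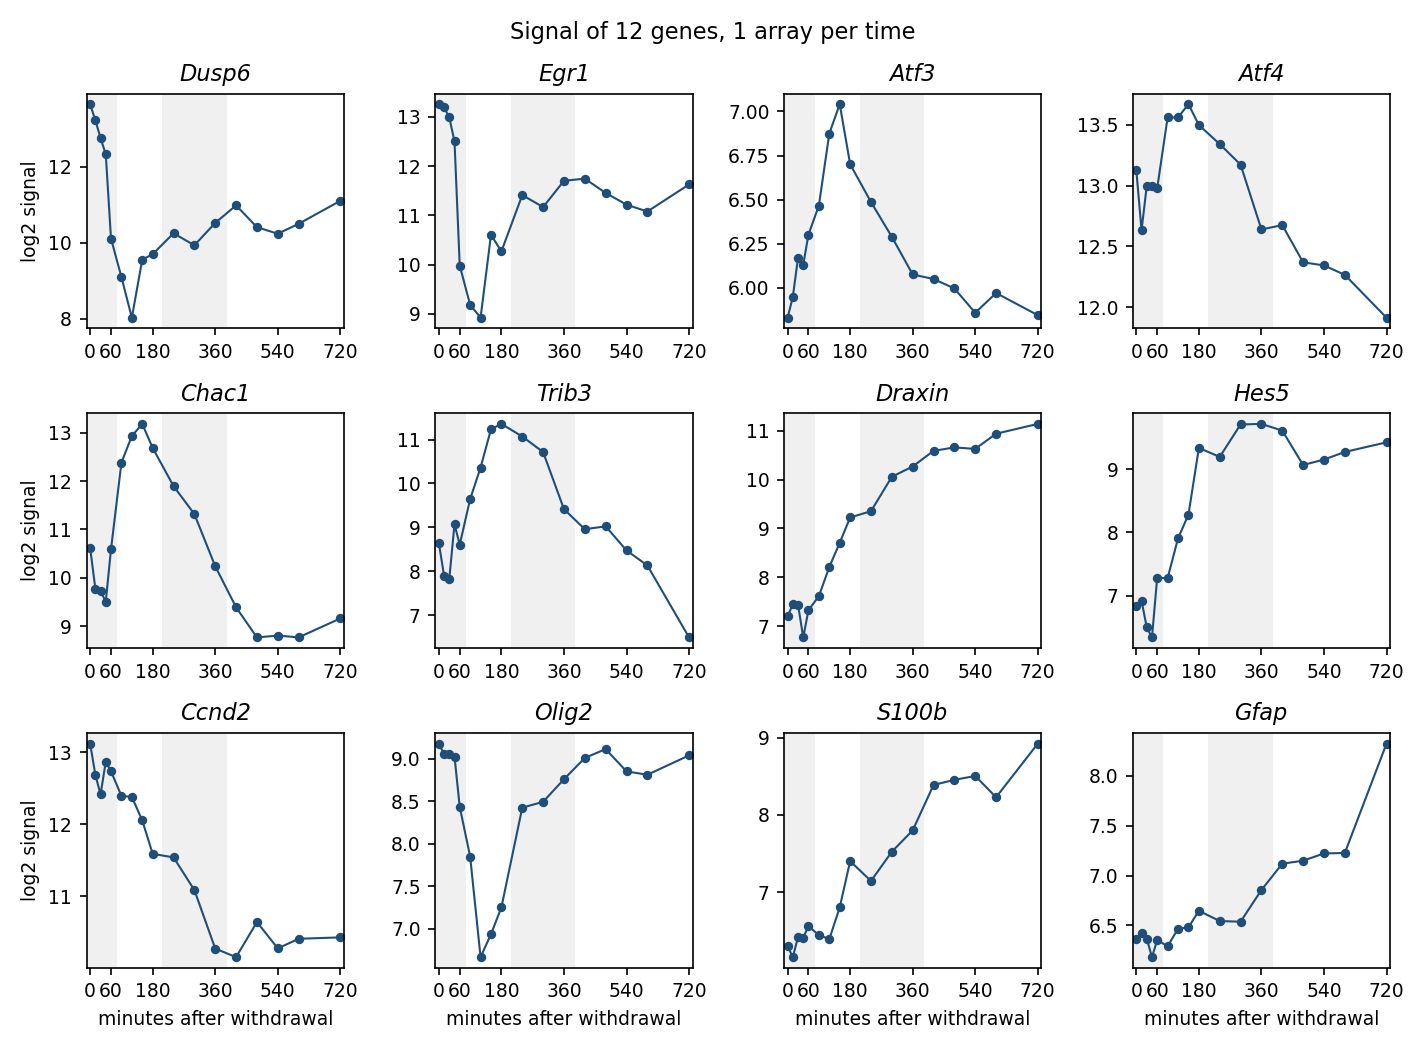
Log2 signal (vertical axes, a separate scale for each gene) of 12 genes against minutes after withdrawal, 1 point per array joined by lines, with the early window and the third shaded. Dusp6 is lowest, at 8.03, at 120 min, Atf3 is highest, at 7.04, at 150 min, and Draxin reaches 11.14 at 720 min.

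The third window, 240 to 360 min, was compared with the early window. Of 9 Notch pathway genes, 6 rose and 3 did not pass (camera adjusted p = 0.000477, and adjusted p = 0.125 with an estimated correlation), with the Notch effector Hes5 6.80-fold higher. Of 26 integrated stress response genes, 16 rose, 2 fell and 8 did not pass (adjusted p = 5.7e-06, and adjusted p = 0.433 with an estimated correlation), with Nupr1 4.58-fold and Trib3 3.98-fold higher. Of 18 ribosome biogenesis genes, 15 fell and 3 did not pass (adjusted p = 8.7e-09, and adjusted p = 0.125 with an estimated correlation). Hes5 went from 6.77 ± 0.37 (SD, n = 5 times) to 9.54 ± 0.30 (n = 3), and since its early signal lay near the filter value of 6.41 its fold is the measured one and not an exact size. Atf4 was at 13.05 ± 0.37 and Atf3 at 6.28 ± 0.21, and neither passed the test against the early window.

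In the third window 3483 features changed, 1693 higher and 1790 lower. The largest rises were in Rhbdl3 (3.10, SE 0.29, adjusted p = 6.1e-08), Hes5 (2.77), the axon guidance gene Draxin (2.65), Retreg1, a receptor for autophagy of the endoplasmic reticulum (2.46), and Ddit4 (2.42). The largest falls were in Pou3f1 (-2.93, SE 0.26, adjusted p = 3.3e-08), Aatk (-2.65), Gbx2 (-2.52), Chst2 (-2.45) and Rhbdf1 (-2.30). Atf4 differed by 0.11 (adjusted p = 0.63), between -0.04 without 240 min and 0.31 without 360 min when 1 array was left out, and Atf3 by 0.21 without the filter (adjusted p = 0.298).

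Adjusted over the list alone, 15 of the 18 ribosome biogenesis and MYC target genes fell in the third window, 19 of the 26 integrated stress response genes rose and 2 fell, and 6 of the 9 Notch pathway genes rose and 1 fell. Stc2 fell by 0.41 and Cebpb fell by 0.76 in the stress response list. In the Notch list, Hes6 rose by 1.47, the ligand Dll1 by 1.36 and the feedback gene Nrarp by 1.11. Of 11 MAPK feedback genes, 8 fell and 1 rose, or 8 and 2 adjusted over the list alone (adjusted p = 0.000577, and adjusted p = 0.264 with an estimated correlation). Of 19 G1/S and DNA replication genes, 9 fell, and 9 adjusted over the list alone (adjusted p = 0.000615, and adjusted p = 0.461 with an estimated correlation). Of 16 FOXO target genes, 10 rose and 1 fell, and the same numbers adjusted over the list alone (adjusted p = 0.00296, and adjusted p = 0.264 with an estimated correlation). Of 14 lysosome and autophagy genes, 6 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.0153, and adjusted p = 0.323 with an estimated correlation).

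The late window, 420 to 720 min, was compared with the early window as the state reached within the series. Draxin rose 11.7-fold, from 7.24 ± 0.28 to 10.79 ± 0.24 (SD, n = 5 times each). Cdkn1c, an inhibitor of cyclin-dependent kinases, rose by a measured 6.26-fold, from 6.60 ± 0.14 to 9.25 ± 0.26. Early means near or below the filter value of 6.41, as in Cdkn1c, Hes5, Igsf11, Fbxo32, Mbp, Pdgfra and S100b, make the late changes of these genes measured differences and not exact sizes. Ccnd2, a D-type cyclin of G1, fell from 12.76 ± 0.26 to 10.38 ± 0.18, and Srm, which makes spermidine, fell from 11.02 ± 0.15 to 8.80 ± 0.10. Atf4 fell from 12.95 ± 0.18 to 12.31 ± 0.27, while Atf3 was at 5.94 ± 0.09 against 6.08 ± 0.19 and did not pass the test.

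In the late window 5458 features changed, 2774 higher and 2684 lower, of which 323 were at least 2-fold higher and 312 at least 2-fold lower. The early and late arrays did not overlap for 3828 features (38.5%). Arrays in random order would give 0.794%, but these are ordered times of 1 series, in which any gradual change raises the share. The largest rises were in Draxin (3.55, SE 0.22, adjusted p = 2.4e-11), Retreg1 (2.84), Rhbdl3 (2.83), Fbxo2 (2.72), Cdkn1c (2.65), Hes5 (2.53), Igsf11 (2.50), the ubiquitin ligase gene Fbxo32 (2.44), Ccng2 (2.35) and Nat8f1 (2.30). The largest falls were in Lor (-2.76, SE 0.13, adjusted p = 8.0e-13), Gbx2 (-2.41), Ccnd2 (-2.38), Pou3f1 (-2.32), Chst2 (-2.29), the glutamate receptor gene Grm5 (-2.27), the bicarbonate transporter gene Slc4a4 (-2.25), the ETS factor Etv4 (-2.23), Srm (-2.22) and Rhbdf1 (-2.20). Atf4 fell by 0.63 (SE 0.13, adjusted p = 0.000247), and Atf3 differed by -0.13 without the filter (adjusted p = 0.428).

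Of 18 ribosome biogenesis and MYC target genes, 17 fell in the late window, and 17 adjusted over the list alone, with Ppan down by -1.58, Rrp9 by -1.46 and Gnl3 by -1.40 (camera adjusted p = 6.2e-09, and adjusted p = 0.125 with an estimated correlation). Of 19 G1/S and DNA replication genes, 17 fell, and 17 adjusted over the list alone (adjusted p = 8.7e-09, and adjusted p = 0.264 with an estimated correlation). Cyclin D1 (Ccnd1), which the MAPK list also holds, fell by 2.11 on the log2 scale. Cyclin E2 (Ccne2) fell by 2.02, Cdc6 fell by 1.88 and Tyms fell by 1.60. Of 18 G2/M and mitosis genes, 0 rose and 3 fell, or 2 adjusted over the list alone, and the list did not pass (adjusted p = 0.605). Of 16 FOXO target genes, 12 rose and 1, Irs2, fell, with the same numbers adjusted over the list alone (adjusted p = 8.9e-05, and adjusted p = 0.125 with an estimated correlation). Pik3ip1 rose by 1.91 and Sesn3 by 1.68. Of 14 lysosome and autophagy genes, 12 rose, and 12 adjusted over the list alone, among them Gabarapl1 (0.97), Wipi1 (0.93), Sqstm1 (0.72) and Ulk1 (0.62). This list had an adjusted p = 0.000531, and adjusted p = 0.214 with an estimated correlation.

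Of 17 sterol and lipid synthesis genes, 14 fell in the late window, and 14 adjusted over the list alone (camera adjusted p = 0.000577, and adjusted p = 0.433 with an estimated correlation). Dhcr7 fell by 1.23, Lss fell by 1.15, Cyp51 fell by 1.14 and Mvd fell by 0.83 on the log2 scale. Of 6 oligodendrocyte lineage markers, 4 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.0152, and adjusted p = 0.268 with an estimated correlation). They were Cnp (2.25), the myelin gene Mbp (1.39), the progenitor receptor gene Pdgfra (1.33) and Cspg4 (0.39). The 2 that did not pass were the lineage factors Olig1 and Olig2. Of all features, 54.9% changed in this window. The filter left out 8 of the 14 markers on the array, and without it 1 of these 8, Enpp6, rose (0.52), while Mog (-0.08), Mag (-0.05), Sox10 (-0.01) and Nkx2-2 (-0.07) were among the 7 that did not pass. Of 9 Notch pathway genes, 6 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.0256, and adjusted p = 0.29 with an estimated correlation). Of 26 integrated stress response genes, 6 rose and 6 fell in the late window, also adjusted over the list alone (adjusted p = 0.987), with Ddit4 at 2.22, Mthfd2 at -1.67 and Chac1 at -1.07. Of 11 MAPK feedback genes, 7 fell and 2 rose, or 8 and 3 adjusted over the list alone (adjusted p = 0.0474, and adjusted p = 0.44 with an estimated correlation). Of 17 ER chaperone and unfolded protein response genes, 10 fell and 3 rose, also adjusted over the list alone, with Creld2 down by -1.19, Calr by -0.91 and Sdf2l1 by -0.82, and Dnajb9 up by 0.59. This list had an adjusted p = 0.0474, and adjusted p = 0.44 with an estimated correlation.

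**Figure D3:**
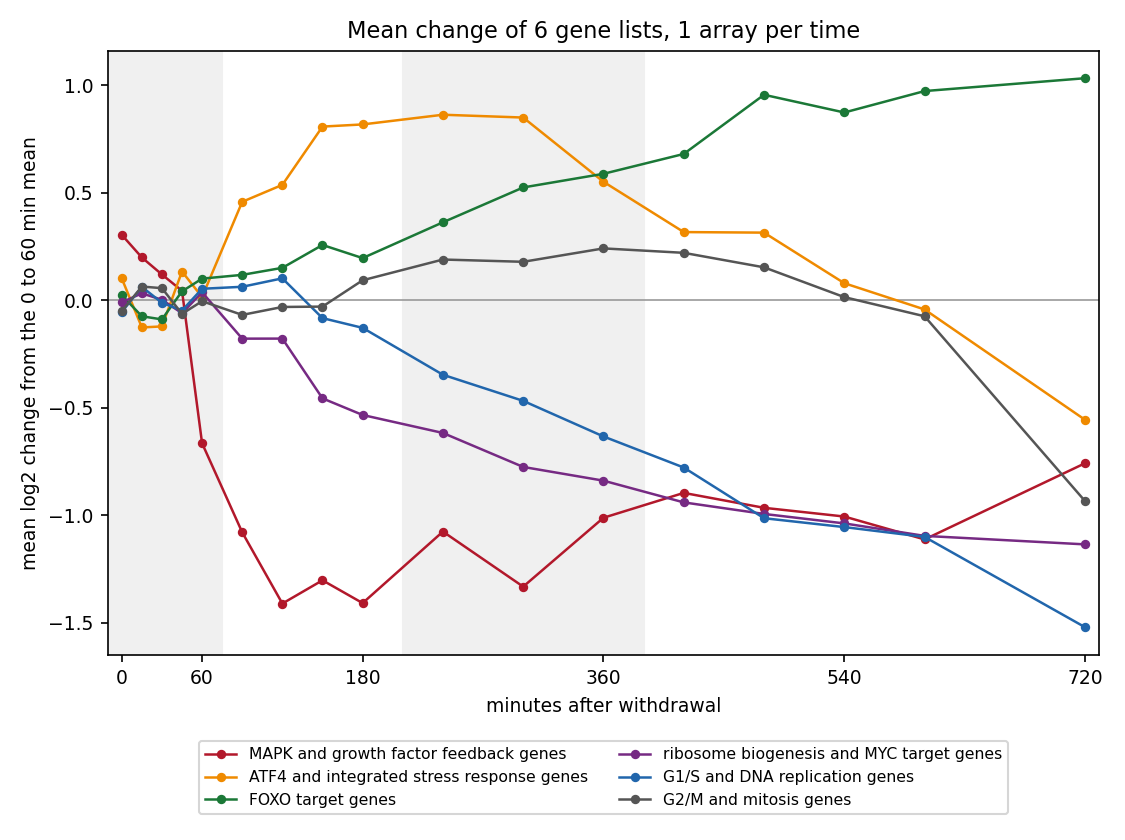
Mean log2 change of the tested members of 6 gene lists from their mean at 0 to 60 min (vertical axis) against minutes after withdrawal, 1 point per array, with the early window and the third shaded. The mean of the integrated stress response list is 0.86 at 240 min, 0.32 at 420 min and -0.56 at 720 min, and the mitosis list is at -0.94 at 720 min.

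With the preset correlation, lineage markers other than those of oligodendrocytes did not pass as lists. With an estimated correlation no lineage list passed (camera adjusted p = 0.268 for oligodendrocyte markers in the late window). Of 11 neuronal lineage markers, 6 rose and 3 fell in the late window, also adjusted over the list alone (camera adjusted p = 0.435). Sox4 rose by 1.99, Prox1, a marker of hippocampal granule neurons, rose by 1.03 and Stmn1 rose by 0.80, while Dlx1 fell by 0.75. The filter left out 13 further neuronal markers on the array, among them Dcx and Tubb3, of which 0 rose and 1, Elavl4, fell (-0.26) without it. Of 11 astrocyte markers, 3 rose and 4 fell, also adjusted over the list alone (adjusted p = 0.959), with S100b up by 2.13 and Cd44 (-1.26), Glul (-0.97) and Slc1a3 (-0.34) down. Of 3 astrocyte markers below the filter, 1, the water channel gene Aqp4, rose (0.75) without it. Of 14 neural stem and progenitor markers, 4 rose and 6 fell, also adjusted over the list alone (adjusted p = 0.895), with Sox2 up by 0.73 and Tnc (-1.58), Nes (-0.89) and Gli3 (-0.78) down. Of the 4 endothelial and mural markers above the filter, 1, Cspg4, rose and 3 fell, Flt1 (-0.76), Acta2 (-0.71) and Tek (-0.36), and the list did not pass (adjusted p = 0.302). Without the filter, 0 of 9 further endothelial and mural markers and 0 of 4 further progenitor markers changed in the late window, while of 4 further Notch genes 2 rose, Dll3 (0.97) and Hey2 (0.24). Among other members below the filter, Chek1 (-0.65) of the G1/S list, Myc (-0.44) and Dkc1 (-0.20) of the ribosome biogenesis list, Epha2 (-0.21) of the MAPK list and Manf (-0.32) of the ER chaperone list fell. Of 12 immediate early genes above the filter, 2 rose and 6 fell in the third window (adjusted p = 0.13), and 2 rose and 4 fell in the late one (adjusted p = 0.442), with the same counts adjusted over the list alone. Of 10 below it, 3 fell in the late window, Arc (-0.32), Maff (-0.29) and Myc, which the ribosome biogenesis list also holds, and 1 rose, Btg2 (0.75), which is also in the p53 list. Of the 11 microglia and macrophage markers on the array, 0 changed without the filter, and the brightest mean was 6.31, at percentile 47.3 of the probes.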

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

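All 17 groups hold 1 array, so no paired analysis was possible because no time was measured more than once. Scaling alternatives moved no array median by more than 0.1 on the log2 scale. For named genes, 3544 of 3587 checks kept direction and side of the threshold, 28 lost the call, 11 gained it and 4 reversed. The 4 came from a straight line in place of the curve, which cannot bend back: Trib3 (-0.53), Chac1 (-1.92), Olig2 (0.31) and Plk2 (0.0245), and 0 transient genes were then found. With only probes above the 75th percentile, fewer features were tested and 3226 changed over time, 655 of them transient, with 553, 1782 and 2872 in the second window, the third and the late one, while the adjusted p was 0.103 for NRF2 genes, 0.188 for ER chaperones, 0.0382 for glycolysis and p53 genes and 0.0264 for astrocyte markers. Without a filter it was 0.00376 for interferon, 0.0382 for glycolysis, 0.0216 for tRNA synthetase and 0.0211 for p53 genes. It was 0.0444 for interferon genes with an intensity trend and 0.0526 for ER chaperones after quantile normalization. With an estimated correlation, 1, 0 and 0 lists passed in the second window, the third and the late one, with 0.125 for ribosome biogenesis, immediate early, FOXO and Notch genes, 0.29 for stress response, 0.264 for G1/S, 0.214 for lysosome, 0.433 for sterol, 0.268 for oligodendrocyte, and 0.44 for NRF2 and ER chaperone genes. An estimate around the spline curve, chosen after seeing the data, lost NRF2 genes in the second window (0.207), MAPK feedback genes in the third (0.0604) and the late one (0.332), and sterol (0.135) and ER chaperone genes (0.18) in the late one, and 6 lists passed in each window. Fry, which does not compare a list with other genes, gave 8 lists in the second window, 14 in the third and 16 in the late one, with 3.9e-05 for interferon, 2.0e-05 for glycolysis, 0.0177 for tRNA synthetase, and 2.9e-06 for endothelial genes in the late window, 0.000863 for p53 genes there, and 0.0129, 0.000911 and 0.000153 for neuronal genes in the second window, the third and the late one. Leaving out 1 array gave 686 to 1315 features in the second window (686 without 180 min), and adjusted p of 0.00788 to 0.0519 for NRF2, 0.0309 to 0.0637 for ER chaperone and 0.0257 to 0.0862 for interferon genes. The causes of these shifts were not tested, except where fewer features or the straight line set them. The pseudocount alternative was not run, since the values were already on a log scale. Low signals limit Atf3 and other genes near the lower end of the range.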

Other observations

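The tests on the number of regroupings, on replication and mitosis genes, and on the stress response were chosen or written after the results were seen, as were the genes singled out at 60 min. The test of bright genes and the power of the first comparison were written before their results were seen.

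When each later array was compared with the arrays at 0, 15 and 30 min, limma called 0 features at 45 min (325 at an unadjusted p under 0.05) and 11 at 60 min. Chance alone gives at least as many features at the unadjusted threshold as were found at 45 min. Each such comparison set 1 array against 3, its spread came from those 3 arrays alone (2 residual degrees of freedom) with limma's moderation across genes, and the lone array was assumed to vary like them. At 60 min the 10 named features were Egr1 (-3.17), Dusp6 (-3.10), Ier3 (-1.83), Irs2 (-1.36) and Plk2 (-1.32), lower than at 0 to 30 min, and Gadd45g (2.06), Arrdc3 (1.44), Gadd45b (1.44), Ddit4 (1.31) and Rasl11b (1.07), higher. The count was 94 at 90 min, 873 at 180 min and 3501 at 720 min.

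Several other lists had members that changed in the late window, but none of these lists passed. Of all features, 54.9% changed in that window. Of 14 p53 target genes in the late window, 4 rose, 2 fell and 8 did not pass (list adjusted p = 0.364). The BH3-only gene Bbc3 (1.71), Sesn1 (1.59), Trp53inp1 (1.37) and Zmat3 (0.31) rose, while Aen (-0.55) and the BH3-only gene Pmaip1 (-0.54) fell. Of 11 clock genes, 4 rose and 4 fell, with Dbp at 0.75 and Bhlhe40 at -1.44 (list adjusted p = 0.987). Of 8 interferon response genes, 5 rose and 0 fell, with Rsad2 at 0.97 and Irf1 at 0.82 (list adjusted p = 0.0549). Of 15 glycolysis and hypoxia genes, 9 fell and 1, Pgk1, rose, with Vegfa at -1.08 and Ldha at -1.01 (list adjusted p = 0.0792). Of 15 tRNA synthetase genes, 7 fell and 2 rose, with Vars at -0.81 and Qars at 0.29 (list adjusted p = 0.13). Of 7 heat shock genes, 2 rose and 4 fell, with Bag3 at 0.87 and Hspd1 at -0.66 (list adjusted p = 0.63). Of 4 BMP and ID response genes, 1, Id2, rose by 0.65 (list adjusted p = 0.702), and of 7 more below the filter 2 rose without it, Id4 (1.58) and Atoh8 (0.33). Of 10 reference genes, 2 rose and 1, Hprt, fell by 0.75 (list adjusted p = 0.895). Below the filter, Btg2 (0.75) of the p53 list, Hspa1a (0.40) and Hspa1b (0.25) of the heat shock list, and Mx2 (0.46) and Usp18 (0.44) of the interferon list also rose without it, and 0 members of the clock, glycolysis, tRNA synthetase and reference lists changed in the late window.

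Counts of genes were higher with the real times than with any regrouping drawn. Neighbouring arrays of 1 series resemble each other, so this cannot tell a response from any other gradual change along the series. For the time course, 1 of 100 assignments of times to arrays, the real one, gave as many as 6152, and the highest other gave 1445. For the second window 1 of 100 splits gave 1154 and the highest other 714, for the third 1 of 56 gave 3483 and the highest other 15, and for the late window 1 of 100 gave 5458 and the highest other 1067. Chance cannot be excluded for the number of lists past the threshold. The other splits passed a median of 3 lists in the second window, 3 in the third and 6 in the late one. A camera call with the preset correlation is therefore weak evidence by itself. In the second window 6 of 100 splits gave as many as the real 7 (highest other 7), in the third 8 of 56 gave as many as the real 7 (highest other 8), and in the late window 20 of 100 gave as many as the real 9 (highest other 11).

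DNA replication genes fell by 1.09 on average in the late window (mean of list, log2), while mitosis genes were at -0.12. A drop in the share of cycling cells that lowers both lists alike and at once would leave no gap, whereas the lists differed by 0.97, a value that restates the pattern and is no separate evidence for it. A difference in signal range is argued against, since 13 mitosis and 11 replication genes of similar early signal kept a gap of 1.10. Its exact permutation p = 0.00794 (two-sided, the smallest 252 splits can give) compares late with early arrays of 1 series. That p does not test signal range. A delay stays open as a hypothesis: the mitosis list declined from 0.24 at 360 min to 0.22, 0.15, 0.01 and -0.07 at 420, 480, 540 and 600 min. It averaged 0.08 from 420 to 600 min and was at -0.94 at 720 min (-0.86 relative to the lowest of those earlier times), with the replication list at -1.52. That last value rests on 1 array, and no biological explanation could be tested against an undifferentiated control.

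The mean of the integrated stress response list rose by 0.65 in the second window and 0.75 in the third. Of its 26 members, 9 and 16 rose, 0 and 2 fell, and 17 and 8 did not pass. The list did not pass with an estimated correlation (camera adjusted p = 0.29 and 0.433). Its mean went from 0.32 at 420 min to -0.56 at 720 min, with 6 members higher and 6 lower in the late window. Stress of the endoplasmic reticulum that raises its chaperone genes as a set is argued against as the source. The chaperone list was at -0.0730 in the second window and -0.18 in the third. Its SDs over the times were 0.10 in the second window and 0.06 in the early one. Of its 17 members 1 rose and 2 fell, then 1 rose and 7 fell. The chaperone list went on to -0.29 in the late window, so a small rise under a steady decline cannot be excluded. Stress that leaves these genes unchanged was not tested. Bright features could rise: 26 of 642 with an early mean of at least 12 rose by more than 0.5. The share among dimmer features was not compared. Of 15 tRNA synthetase genes, 0 rose and 1 fell in the second window, and 2 rose and 1 fell in the third. That list did not pass in either (camera adjusted p = 0.895 and 0.573). It stays open whether an upper limit of the signal held bright synthetase genes back, since dimmer features were not compared. The change of medium or time in culture cannot be told apart from the loss of growth factors, because 0 arrays after 0 min came from cultures kept in growth factors.

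Whether low power explains the absence of calls between 15 to 60 min and 0 min stays open. In simulated data on 9940 features, the comparison of 15 to 60 min with 0 min recovered 87% of changes of 1 on the log2 scale that were present from 15 min, with 10 false calls. Changes that begin at 60 min, as in Egr1 and Dusp6, are diluted by the 3 earlier times, which that simulation did not cover. The simulated noise was the spread around the fitted curves, and most simulated features did not change. In the real comparison, change within the later windows adds to the spread, so 87% may overstate the power.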
